A study of Oryza sativa with 6 samples.

How the data were processed

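Acetylation of histone H3 at lysine 9 (H3K9ac), a chromatin mark found mainly at the promoters of active genes, was profiled in rice (Oryza sativa) seedlings 20 days old. The plants were left uninfested or were infested with the caterpillar Spodoptera frugiperda, the fall armyworm, for 3 h or 12 h. Each of the 3 groups had 2 libraries. Per the labels, nuclei were taken from leaves and the libraries were made by CUT&Tag, in which an antibody directs a transposase to cut and tag the DNA around the mark. The labels also use the term ChIP for the assay. The series design speaks of whole seedlings, and the sample labels were followed. Nothing in the labels says whether replicates came from separate plants or were collected on separate days. Exact permutation tests on values per library therefore measure only the spread between these libraries, which may be technical. Tests that randomise, shuffle or count regions treat regions as replicates and do not measure that spread. The labels name no batch or sequencing date.

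Per the submitters' processing notes, bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and MACS2 2.1.0 were used with genome build IRGSP-1.0. The settings of these tools, the treatment of duplicate reads and the use of an input control are not given in the sources used here. The authors deposited a list of peaks for each library, called per library and not on pooled samples. For each peak the authors deposited the fold enrichment of the summit over the local background of its library, a ratio. The deposited lists also hold the −log10 p-value and the −log10 q-value of each peak and a whole-number score. The smallest −log10 q in any list was 1.30, which corresponds to a q threshold of 0.05. The fold, the q-value and the score are the authors' values for a peak within its own list, and the q-value was used here only to describe, rank or filter peaks of that list. The fold was used in the same way, and also across lists: for rank correlations between libraries at shared regions, for the recovery of summit coverage and local background from the fold and −log10 p, and for the excess fold at shared regions by which infested peaks were rescaled. The score was not used further.

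A stretch of DNA with several summits is listed once per summit, so listed peaks with the same start and end were counted as 1 region. Peaks listed per library include the chloroplast and mitochondrial genomes and unplaced scaffolds; all region counts are for the 12 nuclear chromosomes. Regions of the 6 lists that overlapped by at least 1 bp were merged into a common set, and each list was scored for whether it called each merged region. A region was termed gained when both libraries of the later or treated group called it and neither library of the other group did, and lost in the reverse case. A call that is missing from a list means that the region did not pass the threshold in that library, not that acetylation was absent.

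Read totals were not used here. The depth behind the lists was estimated instead from the deposited fold and −log10 p of each peak, which together give the summit coverage as a whole number and the local background. Whole coverage was recovered for 100% of peaks in every list, with a tolerance of 0.001 on the −log10 p. The lowest local background of a list was taken as its genome background, and was divided by the width of the narrowest region, taken as the fragment length, to give background fragments per kb. The background was 6.52 and 5.25 fragments per kb in the control libraries, 6.27 and 7.17 at 3 h, and 4.31 and 3.84 at 12 h. Median summit coverage lay between 13 fragments in 12 h replicate 2 and 17 in control replicate 1, which limits the precision of each fold and p-value.

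Values per library were compared by exact permutation tests, two-sided; with 2 libraries against 2 the smallest p such a test can give is 0.333, and with 4 against 2 it is 0.133. Adjusted values were computed by the Benjamini-Hochberg method over 15 tests of values per library. Counts of gained and lost regions were compared with 1000 random matrices of regions by libraries, made by swaps that kept the number of lists calling every region and the number of regions in every list. These tests were two-sided, with Benjamini-Hochberg adjustment over 6 counts, and the smallest p they can give is 0.0020. Within each region the randomisation treats the 6 libraries as exchangeable, and it deals every region independently of the others. Regions therefore act as its replicates, and its p-values do not measure the spread between libraries. An excess shows that lists of a group resembled each other more than list lengths alone would give, whatever made them alike. Overlap between lists was set beside 10 shuffles of the regions within their chromosomes. On simulated peaks the recovery of coverage and background succeeded for 100% of 3000 peaks. On simulated matrices of 17468 regions with no effect, 3.33% of 120 tests gave a p under 0.05, and 200 regions planted in the comparison of 12 h with 3 h were detected in 100% of 20 runs. These matrices were drawn from region and list effects alone, as the randomisation itself assumes. They check the procedure and do not show that its p-values hold for the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

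The groups, the tests, the rule for naming regions and most alternative settings were fixed before the data were examined. The plan was written for genes, with merged regions as the fallback. Gene positions on IRGSP-1.0 were not used here, because the gene table at hand belongs to another assembly, ASM3414082v1; assignment of peaks to genes, promoters and gene lists was therefore not analysed here, and the naming rule was applied to regions. Under that rule, the 8 regions of each gained or lost set with the highest lower value of the within-list fold percentile, over the 2 libraries calling them, could be named, and the text gives the leading ones. The chromosome names were assigned from the sequence names of the build, from general knowledge of the assembly.

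Alternatives fixed beforehand were a −log10 q of at least 5, lists shortened to the length of the shortest, merging within 500 bp, overlap of at least 50% of the shorter region, leaving out each library in turn and a replicate block for values per library. Alternatives chosen after seeing the data were a summit coverage of at least 3.5 or at least 6 times the genome background, leaving out regions with a local background over 3 times the genome background, leaving out the neighbourhood of particular regions, widths in regions called in all lists, and a replicate block for the random matrices. The tests by chromosome and by window of 1 Mb, 95% intervals of median percentiles from 2000 resamples of regions, and percentiles among regions called in all 4 infested lists were also chosen after seeing the data.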

Results

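H3K9ac was mapped in leaves of rice seedlings 20 days old that were uninfested or had been infested with the fall armyworm for 3 h or 12 h, with 2 libraries per group. The comparisons ask where the mark is found in uninfested leaves and at which regions calls differ after 3 h and 12 h of infestation. All positions are on build IRGSP-1.0.

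The infested libraries had longer peak lists than the controls at both times. Control lists held 5150 and 5644 peaks, 3 h lists 11738 and 14010, and 12 h lists 12548 and 12167. The means were 5397 ± 349 (SD, n = 2) for control, 12874 ± 1607 (SD, n = 2) for 3 h and 12357.5 ± 269 (SD, n = 2) for 12 h. The 3 h mean was 2.39 times the control mean, a log2 ratio of 1.25, and the 12 h mean was 2.29 times the control mean, a log2 ratio of 1.20. Each difference gave the smallest p of the exact permutation test, 0.333 (adjusted p = 0.556 over 15 tests), so neither could reach 0.05. All 4 infested lists together against both control lists gave an exact p of 0.133, again the smallest possible. The 12 h and 3 h means differed by less than the spread between the 3 h replicates (log2 ratio −0.06; exact p = 1).

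On the nuclear chromosomes the control lists covered 3.27 ± 0.316 Mb (SD, n = 2), the 3 h lists 7.49 ± 0.870 Mb (SD, n = 2) and the 12 h lists 7.77 ± 0.228 Mb (SD, n = 2). The ratio to control was 2.29 at 3 h and 2.38 at 12 h (exact p = 0.333 for each, adjusted p = 0.556), close to the ratios of peak number. With lists of equal length the log2 ratio of covered length went from 1.20 to 0.29 at 3 h and from 1.25 to 0.37 at 12 h. Mean region width was 663 bp in control, 660 bp at 3 h and 696 bp at 12 h. Median width was 576.5 ± 19.1 bp in control, 582.5 ± 4.95 bp at 3 h and 624 ± 32.5 bp at 12 h (SD, n = 2; exact p = 1 for 3 h and 0.333 for 12 h against control). The authors' median fold enrichment per list was 3.64 and 3.78 in control, 3.80 and 3.69 at 3 h, and 4.02 and 4.09 at 12 h. At the 2657 regions called in all 6 lists, called width was 711 ± 32.5 bp in control, 929.5 ± 41.7 bp at 3 h and 924 ± 21.2 bp at 12 h (SD, n = 2), a comparison chosen after seeing the data (exact p = 0.333 for each time against control).

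**Figure D1:**
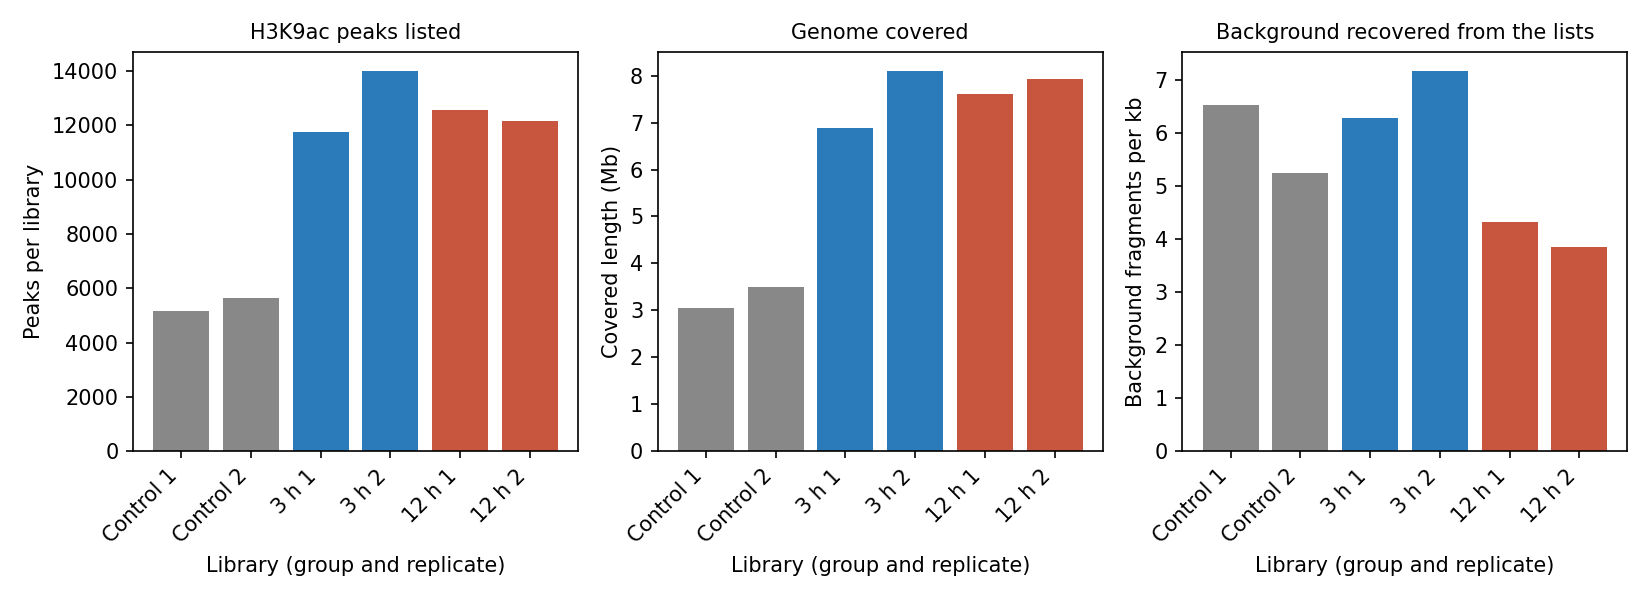
Bars give, for each of the 6 libraries, the number of H3K9ac peaks listed, the covered length of the nuclear chromosomes in Mb and the background in fragments per kb recovered from the lists. Infested lists held 11738 to 14010 peaks against 5150 and 5644 in control, while the background was lowest in the 12 h libraries, at 4.31 and 3.84 fragments per kb.

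Most control regions were also called after infestation. Of the regions of a control list, 83.2% on average (80.8 to 87.1% over 8 pairs of lists) overlapped a region of an infested list. In the other direction, 36.4% (32.7 to 41.4%) of the regions of an infested list overlapped a control region. Replicates shared bases with a Jaccard index of 0.423 in control, 0.498 at 3 h and 0.508 at 12 h. Lists of 3 h and 12 h overlapped almost as much as replicates did (mean 0.471, 0.459 to 0.480), and control and infested lists overlapped less (mean 0.290, 0.255 to 0.336). Regions shuffled within chromosomes gave a Jaccard index of at most 0.0108. With all lists shortened to 5150 peaks, the shares of control regions found in infested lists and of infested regions found in control lists were 56.8% and 56.2%. The mean Jaccard index was then 0.337 between control and infested lists, 0.420 between 3 h and 12 h lists and 0.457 between replicates. Part of the lower index with control thus follows list length, since lists of unequal length cannot reach a high index. The 6 lists merged into 17468 regions, of which 2657 (15.2%) were called in all lists and 5243 (30.0%) in 1 list. Across the 2657 shared regions, which are not independent replicates, the rank correlation of fold between lists was 0.50 for the control pair, 0.64 for the 3 h pair and 0.62 for the 12 h pair. It was 0.56 to 0.60 between 3 h and 12 h lists and 0.38 to 0.48 between control and infested lists.

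After 3 h of infestation, 3384 regions were gained and 94 were lost relative to control. Among the strongest gained regions was chromosome 7 from 3662326 to 3663736, with folds of 6.78 and 6.97 in the 3 h lists. Chromosome 4 from 3766441 to 3767607 had folds of 7.36 and 6.63, and chromosome 2 from 2159995 to 2160821 had folds of 7.18 and 6.45. Chromosome 1 from 41854041 to 41855378 (6.88 and 6.42) and chromosome 10 from 798473 to 799579 (7.41 and 6.42) followed. These regions were called in both 12 h lists as well. All 8 leading gained regions were called in 4 lists, those of the 4 infested libraries. Random matrices gave 2902 gained regions on average (middle 95%, 2845 to 2956) and 20.6 lost regions (13 to 29). Both observed counts lay above every random matrix, with the smallest p the randomisation can give (permutation p = 0.0020, adjusted p = 0.0020). With lists of equal length the gained share of changed regions went from 97.3% to 49.2%, at 546 gained and 564 lost regions, against random means of 310 and 311; equal lengths largely fix that balance. Called without 3 h replicate 1 the gained count was 6545, and the lost count was 432 and 431 without control replicates 1 and 2 and 162 and 237 without 3 h replicates 1 and 2.

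Of the 94 regions lost at 3 h, 28 were called in both 12 h lists, 20 in 1 of them and 46 in neither. Of the 8 strongest, 7 were called in both 12 h lists. Chromosome 4 from 9132954 to 9133590 had folds of 10.2 and 6.66 in control and 14.1 and 9.90 at 12 h, with no call in either 3 h list. On the same chromosome, 9156147 to 9156704 had folds of 5.24 and 6.32 in control and 6.03 and 6.59 at 12 h. Chromosome 2 from 14252954 to 14253430 had folds of 7.46 and 6.29 in control and 9.89 and 7.25 at 12 h. On chromosome 12, the regions 20498888 to 20499832, 20520893 to 20521573 and 20651506 to 20652431 had control folds of 5.33 to 6.99 and were also called in both 12 h lists. Chromosome 4 from 32884955 to 32885525 had control folds of 4.66 and 4.97. Chromosome 10 from 10851289 to 10851697, with control folds of 6.12 and 4.99, was called at 12 h in replicate 2 alone. In the same 3 h libraries the median local background at chloroplast peaks was 3.28 ± 0.130 times the genome background, against 7.78 ± 0.388 in control and 8.16 ± 0.0970 at 12 h (SD, n = 2).

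**Figure D2:**
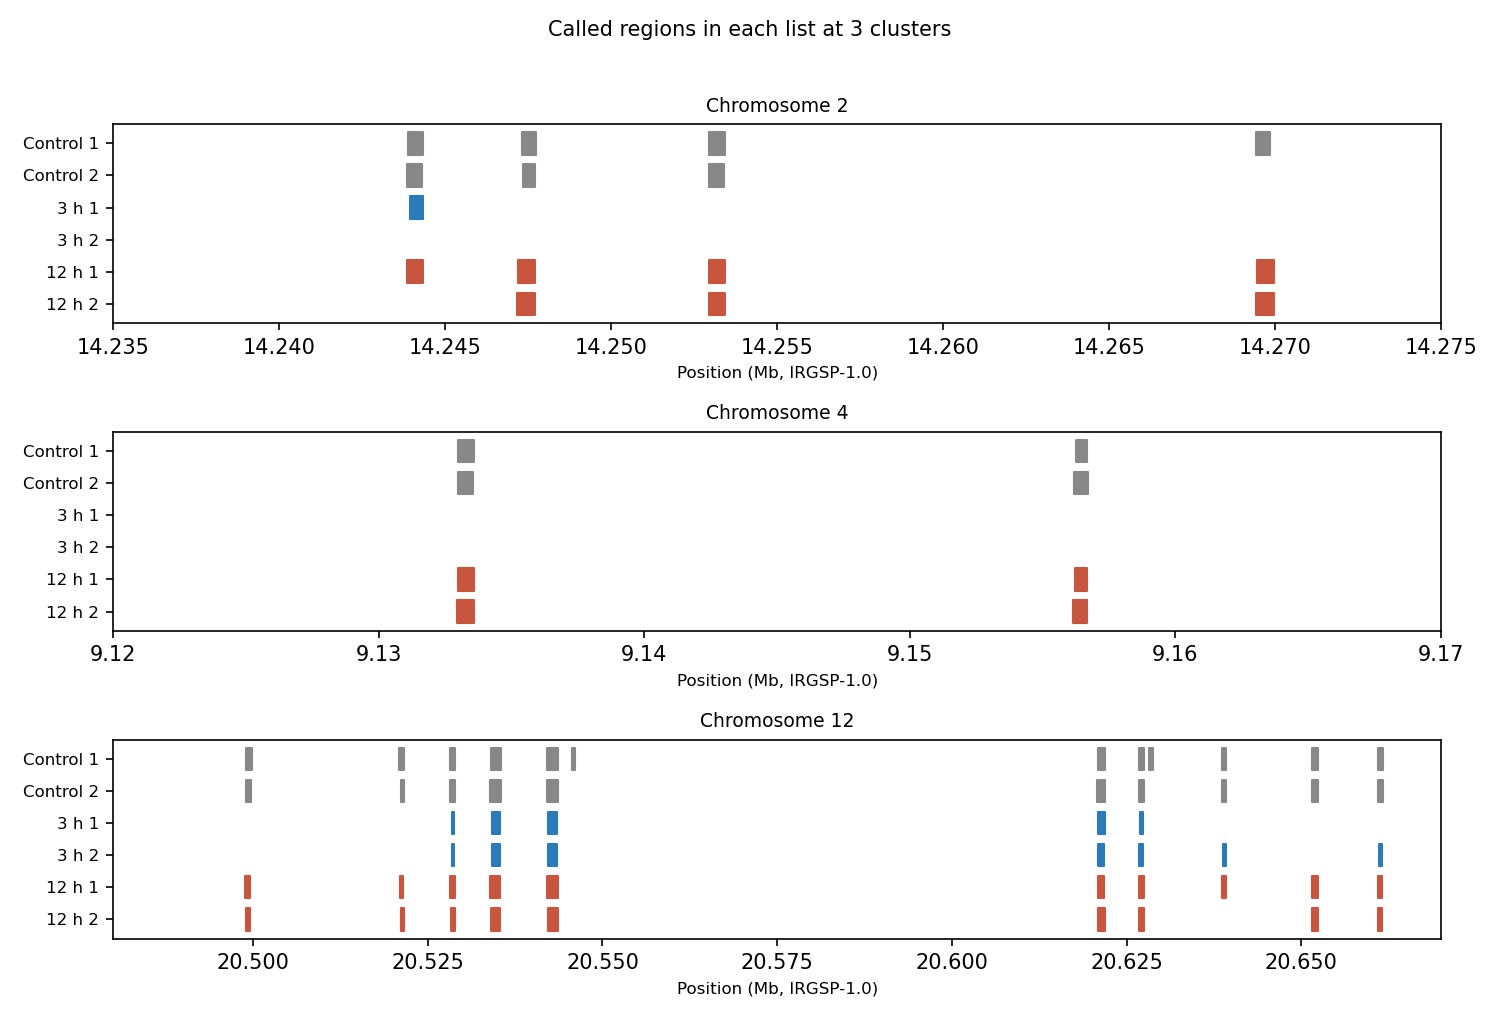
Boxes mark the called regions of each of the 6 lists along parts of chromosomes 2, 4 and 12, with position in Mb on the horizontal axis and a line for each library; the places were chosen after seeing the data. The regions on chromosome 4 from 9132954 and from 9156147 were called in both control and both 12 h lists and in neither 3 h list, whereas several regions on chromosome 12 were called in all lists.

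After 12 h of infestation, 3681 regions were gained and 198 were lost relative to control. The strongest gained region, chromosome 7 from 11268866 to 11269740, had folds of 8.76 and 7.75 at 12 h and of 6.71 and 5.20 at 3 h. Chromosome 3 from 21179885 to 21180750 had folds of 7.33 and 7.79 at 12 h, and chromosome 6 from 10553831 to 10554845 had 7.32 and 7.48. The regions on chromosome 10 from 798473 and chromosome 1 from 41854041, which ranked 5 and 4 in the 3 h set, were also among the 8 strongest at 12 h. Those ranked 1 to 3 at 3 h were not. Chromosome 10 from 10897948 to 10898461 was called in the 12 h lists alone, with folds of 7.15 and 7.09.

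Among the regions lost at 12 h, chromosome 11 from 6287357 to 6288012 had control folds of 6.41 and 6.99 and was called in 3 h replicate 2 with a fold of 4.22. In all, 105 of the regions lost at 12 h were called in both 3 h lists. Chromosome 3 from 25219746 to 25221130 had control folds of 6.26 and 7.05 and 3 h folds of 5.66 and 5.02. Chromosome 8 from 95888 to 96963 had control folds of 5.94 and 5.71. On chromosome 5, the regions 7415292 to 7416535 and 7250183 to 7251363 had control folds of 5.30 to 6.09 and were called in both 3 h lists. Random matrices gave 2890 gained (2833 to 2944) and 21.7 lost regions (14 to 31), and both observed counts lay above every random matrix (permutation p = 0.0020, adjusted p = 0.0020). With lists of equal length the gained share went from 94.9% to 51.4%, at 717 gained and 677 lost regions against random means of 326 and 299. The gained count was 5876 and 5934 without 12 h replicates 1 and 2, and the lost count was 591 and 609 without control replicates 1 and 2 and 309 without 12 h replicate 1.

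Gains at the 2 times overlapped widely. Of the regions gained at 3 h, 2068 (61.1%) were also gained at 12 h, which is 56.2% of the 12 h set. Their median merged width was 903 bp, against 1202 bp for regions called in all lists. A merged region spans the calls of all its lists, so regions called in more lists tend to be wider by construction. Independent sets among the 11043 regions that neither control list called would share 1128, and random matrices gave 1579 (1540 to 1618; permutation p = 0.0020, the smallest possible). The lost sets shared 46 regions, against 5.80 for independent sets among the 3208 regions called in both controls and 2.84 (0 to 6) in random matrices. Both comparisons use the same control libraries, so part of either excess may come from them. Dividing the 2 controls between the times would leave 1 library for each, and this was not run. With lists of equal length the counts were 221 gained and 325 lost at both times, and the lost count was 282 and 324 without control replicates 1 and 2 and 70 without 3 h replicate 2.

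**Figure D3:**
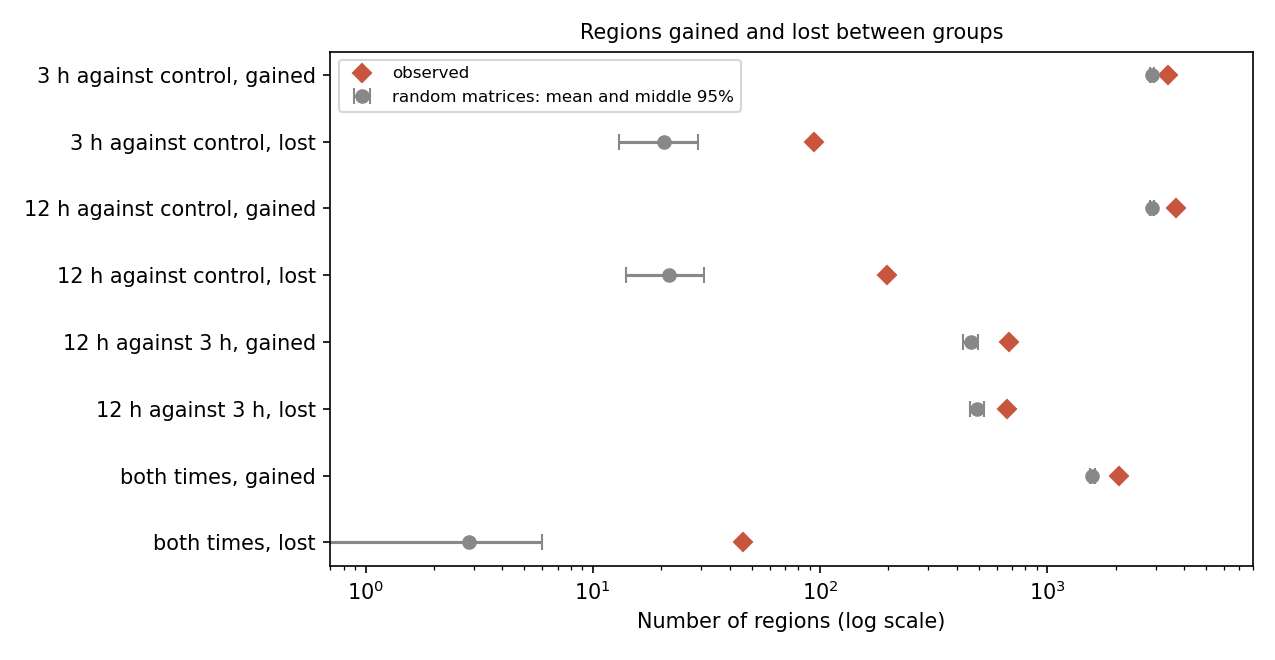
Diamonds give the observed number of regions in each gained or lost set on a log axis, and grey points and bars give the mean and the middle 95% of 1000 random matrices that keep list lengths. Observed counts lay above the bars in all 8 sets, from 46 regions lost at both times to 3681 gained at 12 h; the bar for regions lost at both times reaches 0, beyond the left end of the log axis.

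Between the infested groups, 680 regions were gained and 663 were lost at 12 h relative to 3 h. The strongest gained regions were those on chromosome 4 from 9132954 and chromosome 2 from 14252954, which the control lists also called. Chromosome 2 from 14247161 to 14247732 had folds of 8.73 and 6.99 at 12 h and 4.90 and 4.16 in control. Chromosome 1 from 29081106 to 29082034 (6.54 and 6.38) and chromosome 4 from 4640176 to 4641048 (6.05 and 6.10) were called in the 12 h lists alone. Among the lost regions, chromosome 3 from 21999974 to 22001214 had 3 h folds of 7.12 and 6.74 and was called in both controls. Chromosome 1 from 23607258 to 23608601 had 3 h folds of 6.30 and 5.83. Chromosome 5 from 17433127 to 17433634 (5.44 and 5.13) and chromosome 1 from 4337621 to 4338495 (4.90 and 4.90) were called in the 3 h lists alone. Calls limited to both lists of 1 time numbered 432 at 3 h and 589 at 12 h. Random matrices gave 461 gained (424 to 495) and 490 lost regions (456 to 527), and both observed counts lay above every random matrix (permutation p = 0.0020, adjusted p = 0.0020). At a summit coverage of at least 6 times background, chosen after seeing the data, the gained share went from 50.6% to 77.6%, at 1154 gained and 334 lost regions. That limit is a multiple of each list's own genome background, which had a mean of 1.46 at 12 h and 2.22 at 3 h. It therefore removed more of the 3 h peaks, and the shift cannot be read as a gain at 12 h. Without 3 h replicates 1 and 2 and 12 h replicates 1 and 2 in turn, the gained count was 1108, 1625, 1839 and 1886 and the lost count was 2383, 1636, 1359 and 1268.

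The longer infested lists were spread over the whole genome. The infested mean exceeded the control mean in all 367 full windows of 1 Mb, and every infested list exceeded both control lists in 364 of them. Windows held a median of 12 control regions and 28.25 infested regions, with a median ratio of 2.33. The densest infested window was chromosome 3 from 30000001 to 31000000, with means of 61.25 infested and 20 control regions. The lowest ratio, 1.15, was on chromosome 9 from 4000001 to 5000000 (12 control, 13.75 infested), and the highest, 13.25, was on the same chromosome from 9000001 to 10000000 (1 control, 13.25 infested). Chromosome 4 from 17000001 to 18000000 had no region in either control list and a mean of 4 in the infested lists. Chromosome 3 was the densest chromosome in every group, at 16.7 ± 1.01 regions per Mb in control, 39.2 ± 4.84 at 3 h and 38.3 ± 0.738 at 12 h (SD, n = 2). Chromosome 11 was the sparsest, at 10.2 ± 0.877, 22.5 ± 2.58 and 21.3 ± 0.171 regions per Mb. Chromosome 5 held 7.35 ± 0.358% of control regions, 8.28 ± 0.0133% of 3 h regions and 8.20 ± 0.0234% of 12 h regions (SD, n = 2). That difference gave an exact p of 0.133, the smallest possible (adjusted p = 0.16 over 12 chromosomes). Every chromosome other than 3 and 6 gave the same exact p, so it does not set chromosome 5 apart. Regions gained at both times were 8.75% on chromosome 5, against 7.26% of regions called in all lists (Fisher's exact p = 0.0648, adjusted p = 0.716). No chromosome passed Fisher's test, and none could pass the exact permutation test, so that test decides nothing about shares by chromosome.

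**Figure D4:**
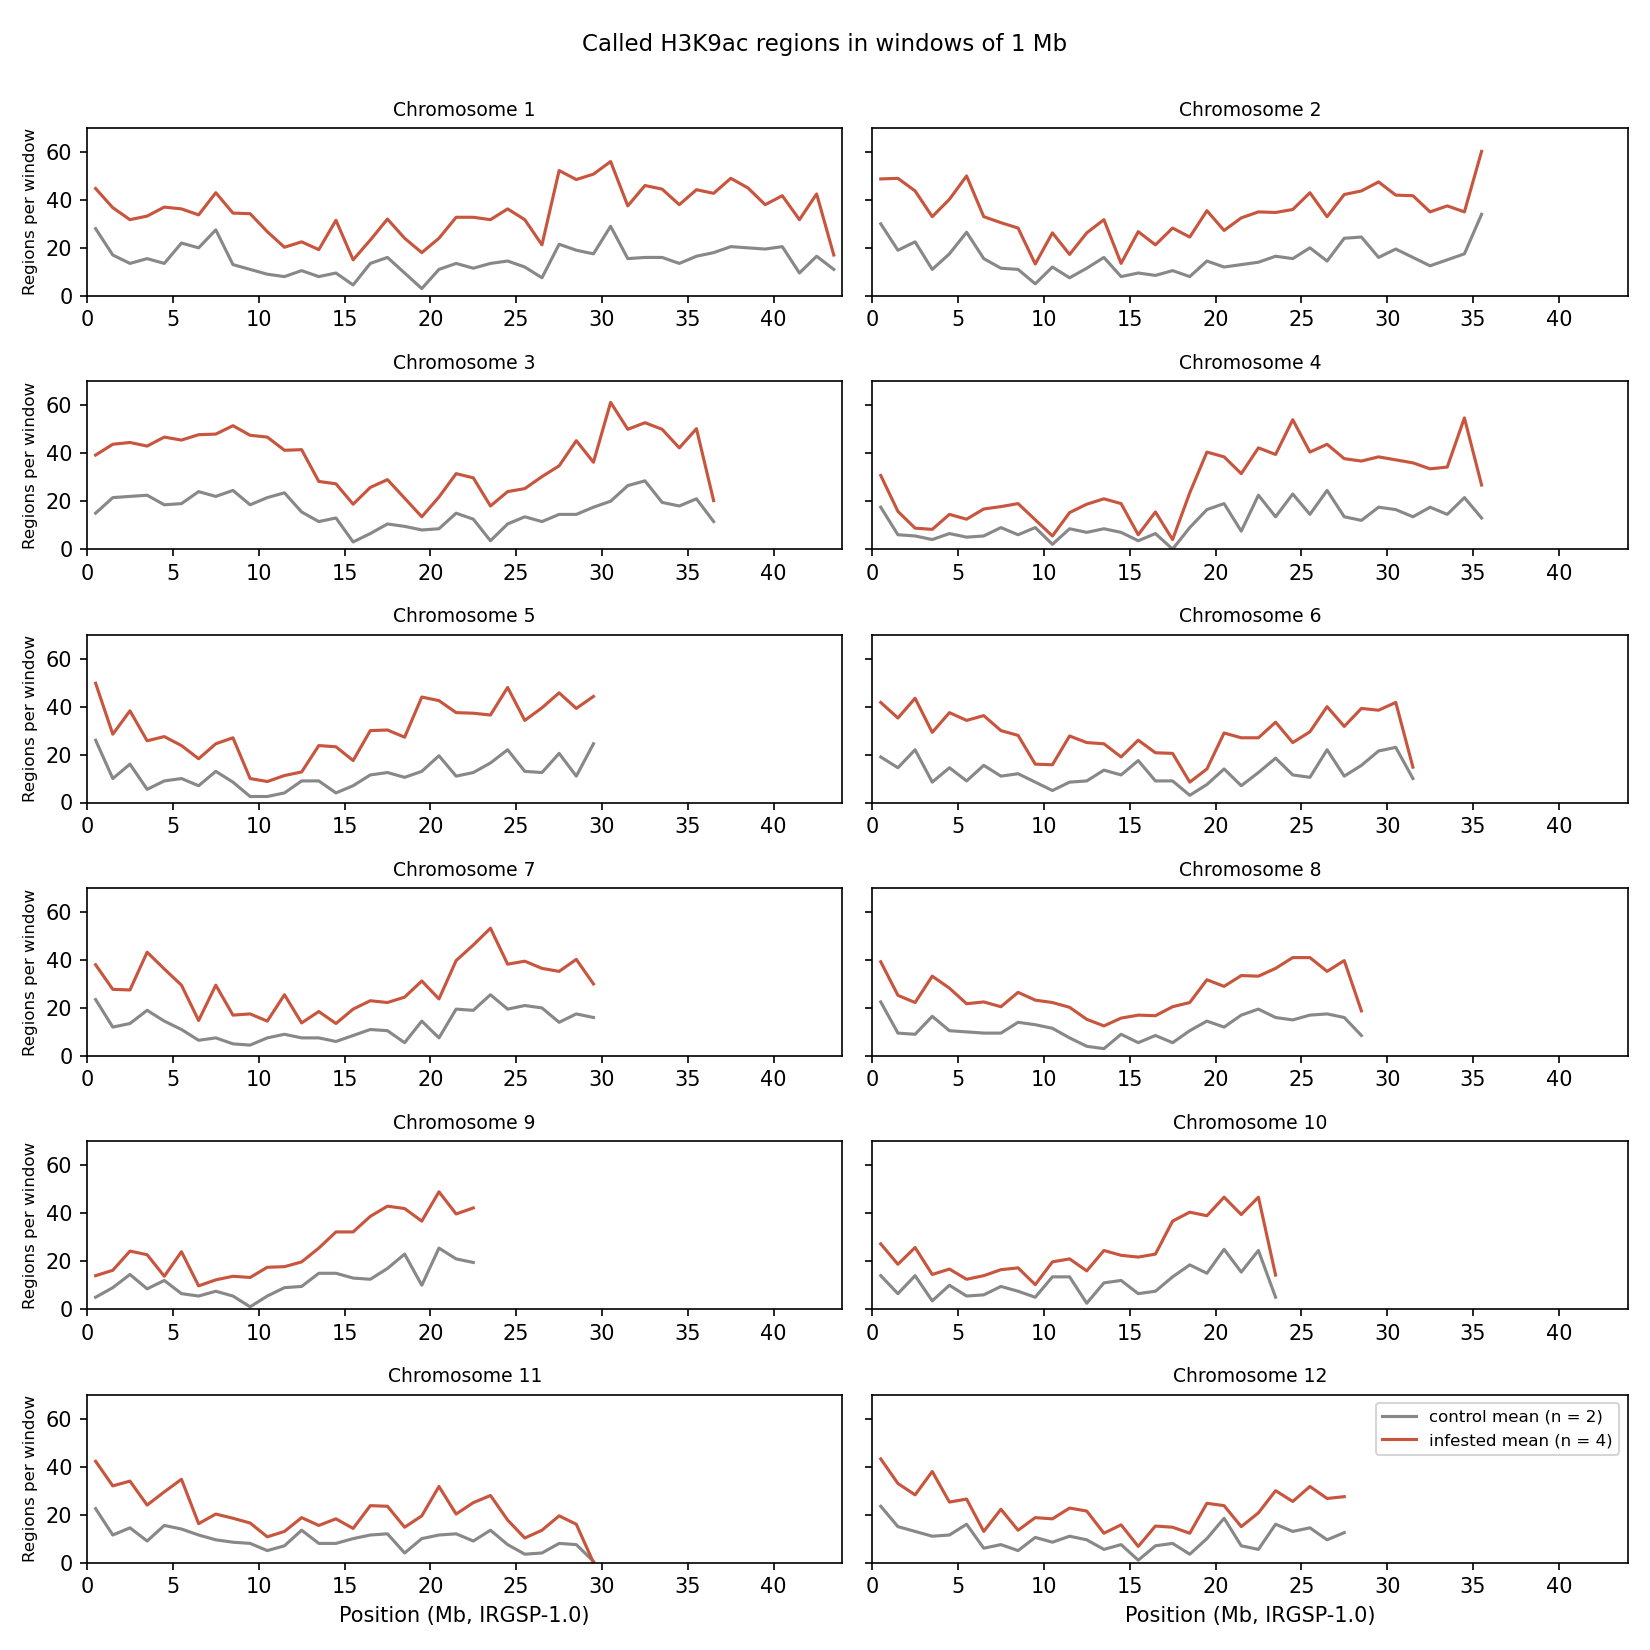
Lines give the number of called H3K9ac regions per window of 1 Mb along the 12 chromosomes, as the mean of the control lists (n = 2) and of the infested lists (n = 4), with position in Mb on the horizontal axis; the last window of a chromosome is shorter than 1 Mb. The infested line lies above the control line in all 367 full windows, with medians of 28.25 and 12 regions.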

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

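The randomisation test of the difference between 12 h and 3 h was planned, and no test was run on the unplaced scaffolds, which were looked at after the data were seen. The 12 h and 3 h groups differed in which regions they called: 680 regions were called in both 12 h lists and neither 3 h list, above the 424 to 495 of the middle 95% of random matrices. In the other direction, 663 regions were called in both 3 h lists and neither 12 h list, above the 456 to 527 of random matrices (permutation p = 0.0020 for each, the smallest possible).

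Outside the nuclear chromosomes, peaks on unplaced scaffolds were more numerous in infested lists, at a mean of 10 against 6.5 in control. As a share of the list the order was the opposite, at 0.120% in control, 0.0819% at 3 h and 0.0768% at 12 h. The control lists held 6 and 7 such peaks, the 3 h lists 10 and 11, and the 12 h lists 10 and 9. Of the 10 scaffolds with a peak, 6 had peaks in infested lists alone, and 1 of these had peaks in all 4 infested lists.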

How the results depend on the processing

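The coverage, local-background, neighbourhood and shared-width settings and the block for random matrices were chosen after the data were seen; the others were planned. All 6 counts of gained and lost regions and both shared counts stayed above random matrices under every list setting run (permutation p = 0.0020, the smallest possible), but their sizes moved. At −log10 q of at least 5, gained regions were 1501 at 3 h, 1596 at 12 h and 733 at both times, and the 12 h against 3 h counts were 420 gained and 431 lost. The Jaccard index was 0.240 between control and infested lists and 0.419 between 3 h and 12 h, and 27.6% of infested regions overlapped a control region. With lists of equal length, gained and lost regions were 546 and 564 at 3 h, 717 and 677 at 12 h and 221 and 325 at both times, and 407 were lost at 12 h against 3 h; the setting removes the weaker calls of the longer infested lists and largely balances gains and losses by construction. The Jaccard indices were then 0.337 and 0.420, and the shares found were 56.8% and 56.2%. Log2 ratios of covered length to control were then 0.29 at 3 h and 0.37 at 12 h. At 6 times background, 12 h against 3 h gave 1154 gained and 334 lost regions and its log2 ratio of peaks reversed to 0.25. The limit is a multiple of each list's own genome background, 1.49 and 1.43 at 12 h and 2.13 and 2.32 at 3 h. It therefore asked for more fragments at 3 h, and it kept 8948 and 9903 peaks there, against 11375 and 10990 at 12 h. The shift follows from the limit and cannot be read as a gain of acetylation at 12 h. The log2 ratio of median width of 12 h to 3 h reversed to −0.0086 at regions called in all lists. Coverage of 3.5 times background was tried before 6 times and removed peaks from 1 list only, so it tests little. Merging within 500 bp and leaving out high local background or the 50 kb around the regions missing at 3 h moved no count of gained or lost regions by more than 1.5 times. Leaving out the 50 kb took the regions lost at 3 h from 94 to 65, by construction, because the regions missing at 3 h belong to that set. Leaving out high local background took the regions lost at 12 h from 198 to 158. Overlap of 50% of the shorter region was run only on the shares of lists found, at 79.8% and 34.7%.

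Leaving out each library in turn, with no test because 1 library then stands for a group, gave these ranges; counts rise because fewer lists must meet the rule. Gained and lost regions were 4127 to 6545 and 162 to 432 at 3 h, 4387 to 5934 and 296 to 609 at 12 h, 1108 to 1886 and 1268 to 2383 for 12 h against 3 h, and 2389 to 3027 and 52 to 324 at both times. Log2 ratios of peaks were 1.12 to 1.38, 1.13 to 1.26 and −0.18 to 0.074 (above 0 without 3 h replicate 2) for 3 h and 12 h against control and 12 h against 3 h. Those of covered length were 1.07 to 1.31, 1.15 to 1.35 and −0.062 to 0.18 (below 0 without 3 h replicate 1). Those of median width were −0.018 to 0.049 (below 0 without control replicate 1), 0.06 to 0.17 and 0.05 to 0.15.

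The replicate numbers did not pair the libraries: differences between replicates 1 and 2 correlated at −0.0081, −0.0045 and 0.0014 between groups. With the replicate number as a block, the log2 ratios of peaks were 1.25, 1.20 and −0.05 (exact p = 0.5, 0.5 and 1, where 0.5 is the smallest possible), and the block changed no call. Random matrices within blocks left the p of the 6 counts at 0.0020. Alternatives planned for genes, promoters and summit location were not run. Depth limits what a missing call means, at a median summit coverage of 13 to 17 fragments.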

Other observations

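The tests of depth, of insect feeding, of adjacency, of the percentile intervals, of ranks among regions called in all 4 infested lists and of short copies of organelle DNA were chosen after the results were seen. For the other tests the prediction was written before the test was run. The set called in control and 12 h but not 3 h lists was not among the planned counts, and its permutation p was not adjusted. Stretches without a called region in any list were found on every chromosome. The longest on chromosome 4 ran 608 kb from 10387340 to 10995387, and that on chromosome 6 ran 545 kb from 18271976 to 18816630, against a median spacing of 12.2 and 12.3 kb on these chromosomes. Neighbouring regions in the merged set were both gained at both times in 284 pairs, against 244 when classes were shuffled within chromosomes (218 to 271; permutation p = 0.0040, adjusted p = 0.0080 over 6 sets). Regions called in all lists formed 466 such pairs against 404, regions lost at 3 h formed 4 against 0.530, and regions lost at 12 h formed 7 against 2.20 (adjusted permutation p = 0.0080, 0.010 and 0.017). Regions lost at both times formed 0 pairs against 0.11 (adjusted permutation p = 1). Mitochondrial peaks numbered 34 ± 4.24 in control, 19.5 ± 6.36 at 3 h and 23.5 ± 6.36 at 12 h (SD, n = 2).

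Control lists held fewer peaks than all 4 infested lists. Lower depth in the control libraries is argued against for 12 h, where their mean background of 5.88 fragments per kb was 1.44 times that of the libraries with the longer lists, but is not settled for 3 h, where it was 0.876 times the 3 h mean of 6.72, while the background coverage before division by the narrowest width was 2.22 in both groups, with no deficit in control. Lower enrichment in the control libraries stays open: excess fold at shared regions was 3.57 and 3.96 in control, 4.27 and 4.18 at 3 h and 4.997 and 4.995 at 12 h, and infested peaks rescaled to the control level still gave 1.93 times the control number of regions. That value passed the limit of 1.5 set beforehand as evidence against this explanation, but the rescaling is a simulated setting and its factor comes from regions the control lists did call, which may understate the gap. It pools both times: 9652 and 11229 regions were left at 3 h and 8636 and 8512 at 12 h, against 4671 and 5174 in control. Genome background was 1.46 at 12 h and 2.22 in control. A summit therefore needed a higher ratio to be called at 12 h, which may raise the excess fold there. An effect of insect feeding cannot be told apart from such a difference in enrichment, because both follow the same groups; the exact p of 0.133 for 4 against 2 libraries is the smallest possible and decides nothing.

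The 28 regions called in both control and both 12 h lists and neither 3 h list exceeded the 11.2 (5 to 18) of random matrices, which argues against list lengths alone (permutation p = 0.0020, the smallest possible; 0.012 with the replicate block), as did 107 against 75.7 (60 to 92.0) with lists of equal length. The size of the set is not fixed: it was 74 and 45 without control replicates 1 and 2, 55 and 117 without 3 h replicates 1 and 2, and 42 and 34 without 12 h replicates 1 and 2. The mirror set, called in both control and both 3 h lists and neither 12 h list, held 105 regions and was not compared with random matrices. A call missing at 1 infested time alone was therefore not particular to 3 h. Reads shared with long repeated sequence are argued against by a median local background of 1.27 times the genome background in control libraries, below the 1.72 of regions called in all lists. That reference may be lenient: in the control libraries 6.70% and 12.1% of its regions passed 3 times the genome background, against 3.57% of the 28 regions in each. Counted over any calling list, the shares were 33.2% of the reference, 10.7% of the 28 regions and 10.6% of all regions. Those shares are not alike, because a region called in more lists has more occasions to pass. The 1.27 also lay below the medians of all nuclear peaks in the control lists, 1.56 and 1.62. Isolated borderline peaks are not settled: the 3 adjacent pairs, against 0.0450 after shuffling, hold 6 of the 28 regions, and median fold percentiles of 69.6 and 48.8 in control and 59.5 and 56.8 at 12 h lie near or above the middle of the lists, with resampled 95% intervals reaching down to 20.8 to 42.3. Copies of organelle DNA no longer than the regions also remain a candidate explanation. On the chloroplast genome the local background was 0.422 times the control value at 3 h and 1.05 times at 12 h. On the mitochondrial genome it was 0.423 times at 3 h and 0.639 times at 12 h. The 12 h replicates differed there, at 3.31 and 1.80 times the genome background. Replicate 2 was near the 3 h values of 1.61 and 1.77, although both 12 h lists called these regions. The mitochondrial value thus does not follow the pattern in both 12 h libraries. No sequence was searched, and a biological effect of 3 h of feeding was not tested separately.

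The 2068 regions gained at both times exceeded random matrices, which argues against list lengths alone. Weak peaks that a shorter control list misses stay open: the median within-list fold percentile of these regions (resampled 95% interval) was 48.2 (46.8 to 49.97) and 54.3 (52.4 to 55.8) at 3 h and 53.3 (51.7 to 55.1) and 53.1 (51.3 to 54.7) at 12 h, and that of all regions gained at each time was 44.9 and 47.8 at 3 h and 45.6 and 45.02 at 12 h. The limit of 50 set beforehand as evidence against weak peaks was passed in 3 of 4 lists but was wrong for this set: its regions had to be called in 4 lists, while 5243 of all 17468 regions were called in only 1, and the 6271 regions called in all 4 infested lists had medians of 62.1 to 66.0. Ranked among those 6271 only, the regions gained at both times had medians of 36.7 to 38.6, and 16.1 to 22.4% of the top 10% of infested regions by fold had no control call against 70.3 to 75.9% of the lowest 10%, but newly acetylated regions of low signal would rank low too. Lower enrichment in the control libraries and insect feeding stay open here as for the list lengths.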
